A study of Mus musculus with 22 samples.

How the data were processed

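RNA was sequenced from primary splenic monocytes of wild-type male C57BL/6 mice and from macrophages made from such monocytes in culture with phorbol myristate acetate (PMA, 200 ng/mL for 5 days). Per the labels, cells of both kinds were then given vehicle or oxidised low-density lipoprotein (ox-LDL, 50 µg/mL for 24 hours). Libraries were made from polyadenylated RNA with a SMARTer low-input kit, and the kit, tissue, sex and doses come from the labels. The strain comes from the series description.

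The authors aligned the reads with STAR 2.7.9a to the mouse genome GRCm38 and counted them per gene with featureCounts 2.0.3 from Subread. The deposited table of each of the 22 libraries gives counts, CPM, FPKM and TPM for 55487 Ensembl genes. The deposited counts are whole reads per gene with no normalization. The deposited CPM are those counts scaled to a library total of 1000000, the deposited FPKM are that CPM per kilobase of gene length, and the deposited TPM sum to 1000000 per library. These relations were checked on every gene of every library, and 0 genes departed from them. The strand setting, the treatment of reads that map to several places and the release of the annotation are not given in the sources used here. Reads in overlapping or antisense genes, and reads shared by near-identical genes (Apol7a and Apol7c, the haemoglobin genes, Ifit3 and its copy, the Rn7sk copies), could not be assigned from the tables. Gene positions are those of the deposited tables, and 99.4% of the genes shared with GENCODE M21 had the same start and end there.

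All fits started from the counts, and the deposited CPM, FPKM and TPM were not used here beyond the check. The 22 libraries fell into 4 groups by the labels: 6 of monocytes with vehicle, 5 of monocytes with ox-LDL, 5 of macrophages with vehicle and 6 of macrophages with ox-LDL. No library was left out. The labels do not say whether libraries of a group came from separate mice or separate cultures, so the p-values measure the spread between these libraries only, which may be technical. Totals ran from 37.3 to 50.3 per library, in units of 1000000 counts. A floor of 3 counts over a group was used where a group had no counts, and such bounds cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

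The design, the named genes' rule, the gene lists and the alternative settings were chosen before the data were examined. Each comparison was fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, the default filter on low counts (filterByExpr), a quasi-likelihood F test, 2-sided, and Benjamini-Hochberg adjustment over the genes tested. A gene with an adjusted p under 0.05 is said to be called. The 5 comparisons were ox-LDL against vehicle in monocytes, the same in macrophages, macrophages against monocytes with vehicle, the same with ox-LDL, and the difference of the ox-LDL effect between the cell types (an interaction contrast over all 4 groups). No covariate entered, since the labels give no batch. Errors of log2 fold changes are standard errors from the F statistic. CPM in the text are computed here with TMM factors over all 22 libraries and are given with their SD.

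Gene lists were tested with camera in limma 3.58.1, which asks whether the genes of a list moved further in a direction than the other genes tested. The preset correlation between genes was 0.01, the values were log2 CPM with a prior count of 2, and lists needed 5 tested members. The p-values were adjusted over the lists of a comparison. There were 31 lists: sterol synthesis and uptake, LXR targets and efflux, lipid storage and fatty acid use, scavenger and lipoprotein receptors, macropinocytosis machinery, NRF2 antioxidant genes, inflammatory cytokines, interferon response, ER and integrated stress, lysosome, cell cycle, MHC class II, adhesion and migration, matrix and proteases, glycolysis and hypoxia, oxidative phosphorylation, immediate-early and heat-shock genes, mitochondrial transcripts, and markers of monocytes, macrophages, B cells, plasma cells, T cells, NK cells, neutrophils, dendritic cells, erythroid cells, platelets, stroma, endothelium and mast cells. They were written from general knowledge, not from these libraries, and some genes stand in more than 1 list.

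Named genes followed a rule. For each comparison it took the 8 highest and 8 lowest fold changes among called genes with a mean of at least 5 CPM, non-overlapping groups and an assigned gene name that is not an immunoglobulin or T-cell receptor segment. For each list it took up to 4 called members, or the 2 with the highest mean CPM where none was called. A set of 16 genes of lipid uptake, efflux and monocyte biology was named in both ox-LDL comparisons. For the difference of effects it took 4 in each direction. Genes named outside the rule are said to be so. Some genes that the rule names are not reported here, and they stay in the counts and list tests.

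The alternative settings were size factors as in DESeq2 (RLE), total counts only, no filter on low counts, a stricter filter of 5 CPM, DESeq2 1.42.0, limma voom with quality weights, 1 fit over all 4 groups, a 2-fold threshold, immunoglobulin, T-cell receptor and haemoglobin genes left out, an estimated correlation for the lists, and each library left out in turn. After the data were seen, covariates were added: 2 or 3 sets of libraries per cell type from Ward clustering of the 1000 genes with the highest residual variance, 3 sets of macrophage libraries read by eye from the principal components, and surrogate variables (sva 3.50.0). Fits without the smaller set of libraries of each cell type were added as well. The fits without covariates remain those reported. Up to 100 splits of the libraries into groups of the same sizes were fitted for each comparison. The fits were also tested on simulated data with known changes made from these libraries: in each comparison 50 genes were changed by each of 4 sizes. At a 2-fold change 44% of the changed genes were recovered in monocytes, 68% in macrophages and 36% in the difference of effects. At 1.5-fold the recovery was 4%, 46% and 6%. The simulated counts were drawn independently for each gene around 1 mean shared by all libraries of the comparison. They held no library sets and, beyond the known changes, no difference between cell types, so recovery in the real libraries may differ. Tables were read with pandas 2.3.3 and plotted with matplotlib 3.10.9 in Python 3.11.15.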

Results

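Transcript levels were measured by RNA sequencing in splenic monocytes and in PMA-differentiated macrophages, each with vehicle or ox-LDL, the oxidised lipoprotein that loads myeloid cells with cholesterol. There were 6 monocyte libraries with vehicle (replicates 1 to 6), 5 with ox-LDL (7 to 11), 5 macrophage libraries with vehicle (A to E) and 6 with ox-LDL (G to L). In units of 1000000, total counts ran from 42.0 to 48.3 per library in vehicle monocytes, 38.9 to 48.8 in ox-LDL monocytes, 37.3 to 50.3 in vehicle macrophages and 40.7 to 49.6 in ox-LDL macrophages. Monocyte libraries held counts for 23860 ± 364 genes with vehicle (SD, n = 6) and 23204 ± 510.0 with ox-LDL (n = 5), macrophage libraries for 20977 ± 307 (n = 5) and 20860 ± 319 (n = 6). Mitochondrial genes took 0.262% and 0.273% of counts in monocytes and 0.13% and 0.111% in macrophages. The first principal component of all 22 libraries held 78.8% of the variance and separated the cell types.

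The monocyte libraries held abundant transcripts of genes listed as markers of other cell types. Their cells of origin were not measured, and the labels name no sort or gate. The summed neutrophil markers (such as Ngp, a granule protein, and S100a8) reached 17210 ± 18040 CPM with vehicle (SD, n = 6) and 18220 ± 18000 with ox-LDL (n = 5), against 232 ± 54.4 and 239 ± 85.3 in macrophages. Dendritic cell markers summed to 11170 ± 1869 and 9900.0 ± 1410 CPM in monocytes and to 609 ± 44.4 and 556 ± 35.5 in macrophages. Erythroid markers summed to 6111 ± 4409 and 9057 ± 5363 CPM in monocytes and to 2.89 ± 0.984 and 2.60 ± 0.771 in macrophages, and B-cell markers to 1538 ± 839 and 1150.0 ± 549 against 78.7 ± 7.48 and 70.5 ± 9.45. Within monocytes, replicates 5, 6, 10 and 11 held 30580 to 46450 CPM of neutrophil markers and the other 7 held 4989 to 6131. Replicates 1, 2 and 7 were the lowest in erythroid markers. Both sets crossed the treatment groups.

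**Figure D1:**
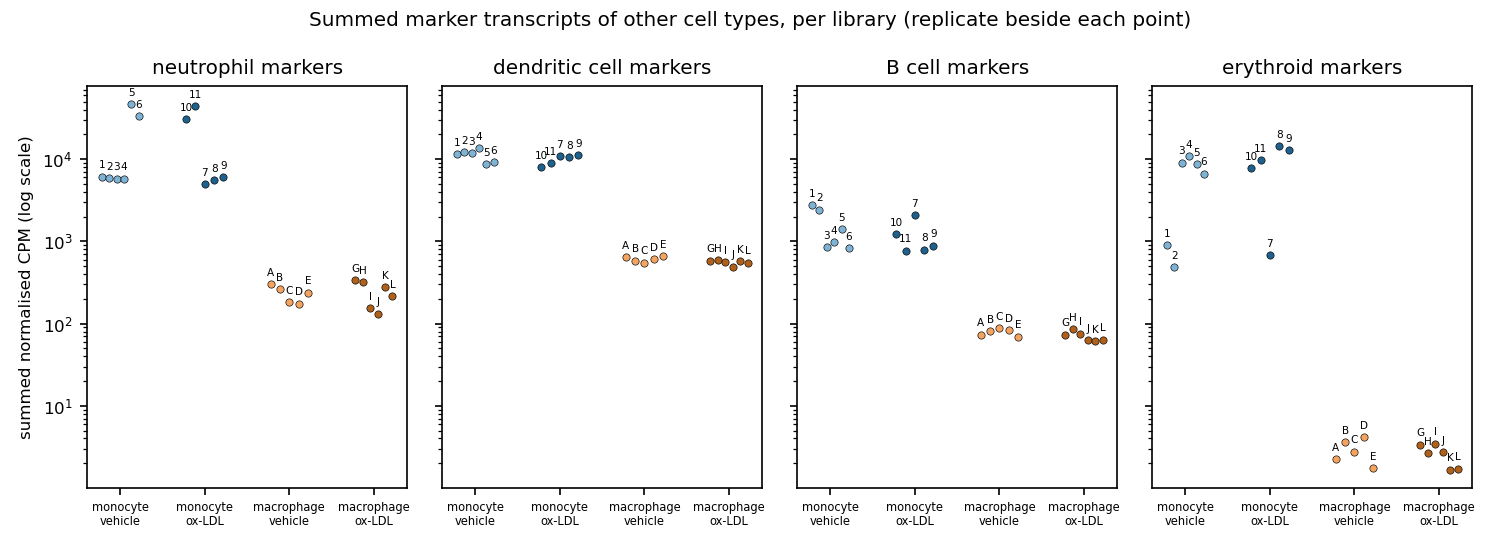
Summed normalised CPM of markers of neutrophils, dendritic cells, B cells and erythroid cells (log axis), 1 point per library with its replicate beside it. Replicates 5, 6, 10 and 11 lie between 30580 and 46450 CPM in neutrophil markers and the other monocyte libraries between 4989 and 6131.

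The comparison of ox-LDL with vehicle in monocytes asked which genes differ between foamy and non-foamy monocytes. Transcripts of 4 genes rose. Cd36 (ENSMUSG00000002944; GRCm38 chromosome 5, 17781690 to 17888801), a scavenger receptor that takes up ox-LDL, rose from 271 ± 67.7 CPM (SD, n = 6) to 793 ± 219 (n = 5), a log2 fold change of 1.58 ± 0.22 (SE; adjusted p = 0.0263). Plin2 (ENSMUSG00000028494; chromosome 4, 86648386 to 86670060), which coats lipid droplets, rose from 534 ± 51.1 to 1199 ± 305 CPM, 1.19 ± 0.17 on the log2 scale (adjusted p = 0.0263). Akr1b8 (ENSMUSG00000029762; chromosome 6, 34354119 to 34368463), an aldo-keto reductase, rose by 1.57 ± 0.21 on the log2 scale from 13.2 ± 2.18 to 38.5 ± 12.9 CPM. Mmp12 (ENSMUSG00000049723; chromosome 9, 7344381 to 7369499), a macrophage elastase, rose by 1.35 ± 0.18 from 104 ± 23.0 to 258 ± 54.6 CPM, both with the same adjusted p. In all 4, each ox-LDL library lay above each vehicle library.

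These were 4 of 16575 genes tested with edgeR, 4 higher and 0 lower, while 1718 (10.4%) had an unadjusted p under 0.05. The groups did not overlap in 231 genes (1.39%), where chance gives 0.43%. Several other fits called lower genes too: 94 higher and 67 lower with DESeq2, 22 and 8 with limma voom, 150 and 109 in 1 fit over all 4 groups, and, in fits added after the data were seen, 85 and 37 with 2 library sets as a covariate, 140 and 87 with 3 and 568 and 483 with surrogate variables. The calls were lost, with 0 genes called, without any one of vehicle replicates 1, 2, 4, 5 and 6 or ox-LDL replicates 8, 9 and 11. Without replicate 3 there was 1 call, without replicate 7 there were 7 (7 higher and 0 lower) and without replicate 10 there were 8 (6 higher and 2 lower). Without the 4 libraries high in neutrophil markers, a fit added after the data were seen, 0 genes were called by edgeR and 2689 had an unadjusted p under 0.05. There the log2 fold changes were 1.39 ± 0.20 for Cd36 and 1.30 ± 0.20 for Plin2, with an adjusted p of 0.0846 for both. Over all alternatives the adjusted p of Cd36 ran from 9.76e-08 to 0.123.

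Among the gene lists in monocytes, the NRF2 antioxidant genes, which protect against oxidants, moved higher (camera adjusted p = 8.18e-10; adjusted p = 0.183 with an estimated correlation). Of its 25 members 0 were called by edgeR and 11 were higher when adjusted over the list alone, and the ferritin genes Fth1 (0.51 ± 0.21, adjusted p = 0.426) and Ftl1 (0.53 ± 0.15, 0.267) had the highest levels. The lysosome list moved higher (3.07e-08; adjusted p = 0.143 with an estimated correlation), with 0 of 32 called, 7 higher when adjusted over the list alone, and Ctsb, a cathepsin, at 0.66 ± 0.17 on the log2 scale (adjusted p = 0.22). Lipid storage and fatty acid use moved higher (1.92e-04; adjusted p = 0.143 with an estimated correlation), with Plin2 called among 25 and 4 when adjusted over the list alone. The interferon response list moved lower (3.01e-08; adjusted p = 0.128 with an estimated correlation), with 0 of 31 called and 4 lower when adjusted over the list alone; its most abundant members, Gbp2 at -0.24 ± 0.17 and Usp18 at -0.01 ± 0.21, were not called. The median of the 25 NRF2 members was 0.50 on the log2 scale, of the 32 lysosome members 0.27 and of the 31 interferon members -0.33. Library sets as a covariate, chosen after the data were seen, raised the edgeR calls in these lists. With 2 sets, 8 NRF2, 4 lysosome and 3 lipid storage members were called higher and 4 interferon members lower. With 3 sets these counts were 8, 5, 3 and 6.

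Other lists moved in monocytes with a higher camera adjusted p than the lists above. Sterol synthesis and uptake moved lower (adjusted p = 0.0196), with 0 of 24 called and 1 lower when adjusted over the list alone. MHC class II (0.02, 0 of 16 called) and B-cell markers (0.00473, 0 of 18 called) moved lower too. Higher were ER and integrated stress (0.0327; 0 of 23 called), oxidative phosphorylation (0.00441; 0 of 28 called), matrix and proteases (0.0292; Mmp12 called among 18) and macrophage markers (0.0292; 0 of 21 called). With an estimated correlation these gave adjusted p of 0.697, or 0.75 for B-cell markers and oxidative phosphorylation, and no list was called in monocytes. Among macrophage markers, the lectin gene Lgals3 stood at 0.81 ± 0.15 on the log2 scale (adjusted p = 0.0823) and Gpnmb at 1.09 ± 0.30 (0.253). In the sterol list Srebf2, a sterol-regulated transcription factor, stood at -0.83 ± 0.18 (adjusted p = 0.164).

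The macropinocytosis list, genes of the uptake of fluid by membrane ruffles that the series title names, was not called in monocytes (adjusted p = 0.9; 0 of 41 called, 0 when adjusted over the list alone). The median of its members was -0.02 while the camera direction was up. LXR targets and efflux were not called either (adjusted p = 0.729; median 0.02, mean -0.01), with Abcg1 at 0.68 ± 0.16 (adjusted p = 0.212) and Abca1 at -0.19 ± 0.32 (0.896), both cholesterol exporters. Of the other preset genes, Msr1, Hmox1, Il1b, Ly6c2, Ccr2, Adgre1, Csf1r, Pak1 and Cybb were not called in monocytes and had adjusted p from 0.236 (Msr1, 0.84 ± 0.22) to 0.974 (Cybb, -0.07 ± 0.34). Some of these depended on the fit. With DESeq2, in 1 fit over all 4 groups, and with 2 or 3 library sets or surrogate variables as covariates, Msr1, Abcg1, Ctsb, Gpnmb, Lgals3 and Srebf2 were called in the directions given, and Lgals3 and Srebf2 with limma voom as well. Ccr2 was called lower with 3 sets (-0.52 ± 0.11, adjusted p = 0.0419) and with surrogate variables, and Ly6c2 with surrogate variables alone. Over 22 alternatives the adjusted p ran from 0.00577 to 0.507 for Msr1 and from 0.0392 to 0.91 for Ccr2.

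**Figure D2:**
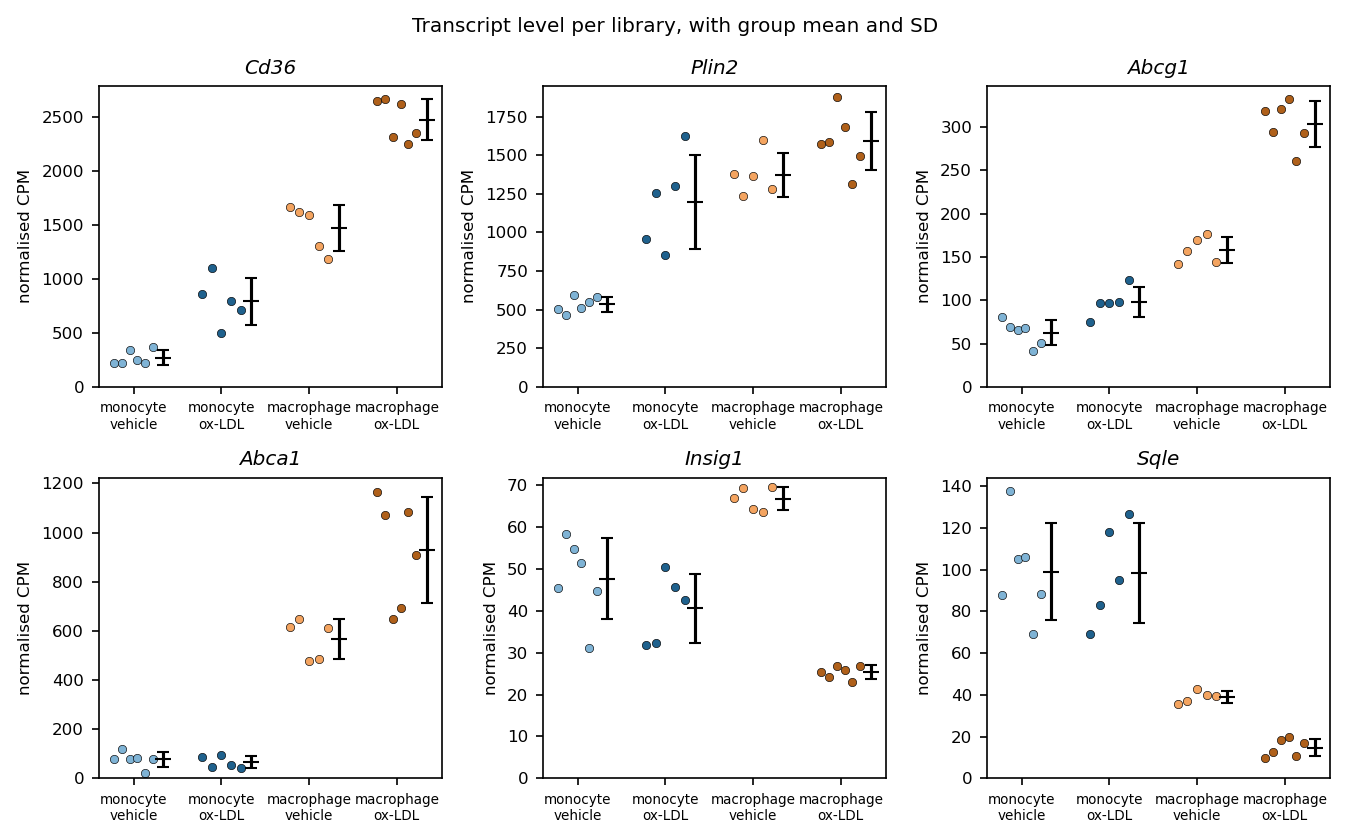
Normalised CPM of Cd36, Plin2, Abcg1, Abca1, Insig1 and Sqle, 1 point per library, with the group mean and SD as bars (n = 6, 5, 5 and 6). Insig1 averages 66.7 CPM in vehicle macrophages and 25.4 in ox-LDL macrophages, and 47.7 and 40.7 in monocytes.

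The comparison of ox-LDL with vehicle in macrophages asked the same of foam macrophages. Genes of sterol synthesis and uptake fell. Insig1 (ENSMUSG00000045294; chromosome 5, 28071363 to 28078662), which holds SREBP proteins in the ER, fell from 66.7 ± 2.74 CPM (SD, n = 5) to 25.4 ± 1.59 (n = 6), a log2 fold change of -1.39 ± 0.06 (adjusted p = 2.48e-08). Of the 24 members tested, 19 fell, 0 rose and 5 were not called, or 23 fell when adjusted over the list alone. Examples were the enzymes Sqle (-1.40 ± 0.17), Cyp51 (-1.20 ± 0.11) and Mvd (-0.95 ± 0.08). The list moved lower by camera (adjusted p = 1.03e-39; adjusted p = 7.54e-04 with an estimated correlation).

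Cholesterol efflux genes and Cd36 rose in macrophages. Abcg1 (ENSMUSG00000024030; chromosome 17, 31057675 to 31117988) rose from 158 ± 15.2 to 304 ± 26.3 CPM (0.94 ± 0.08 on the log2 scale, adjusted p = 7.47e-05). Abca1 rose from 567 ± 79.7 to 929 ± 217 CPM (0.71 ± 0.15, 0.0281) and Mylip, a ubiquitin ligase, by 0.57 ± 0.10 (0.00956). These were 3 of the 17 LXR targets tested, 6 when adjusted over the list alone, and the list moved higher (adjusted p = 7.15e-04; adjusted p = 0.0174 with an estimated correlation). Cd36 rose from 1473 ± 211 to 2475 ± 188 CPM (0.75 ± 0.10, adjusted p = 0.0013). It was the called member among 19 scavenger and lipoprotein receptors, a list that was not called (0.394). Plin2 was not called (1373 ± 141 and 1589 ± 188 CPM; 0.21 ± 0.09, adjusted p = 0.312), nor was the scavenger receptor Msr1 (0.02 ± 0.12, 0.973).

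NRF2 antioxidant genes rose in macrophages: 9 of 25 were called higher and 0 lower, or 17 when adjusted over the list alone. Srxn1 (0.63 ± 0.08, adjusted p = 0.00146), Prdx1 (0.61 ± 0.09), Txnrd1 (0.54 ± 0.08) and Cat (0.55 ± 0.09), all of peroxide and thiol defence, were among them. The list had a camera adjusted p of 2e-15 and an adjusted p of 0.0705 with an estimated correlation. ER and integrated stress moved higher as a list (0.00134; adjusted p = 0.0174 with an estimated correlation), with the chaperone Hsp90b1 called higher (0.35 ± 0.08) and Sesn2 called lower (-0.46 ± 0.11) among 23. The lysosome list moved higher (0.00157; adjusted p = 0.283 with an estimated correlation), with Psap, which encodes saposins, called among 32 (0.71 ± 0.16, adjusted p = 0.0356) and 7 when adjusted over the list alone.

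Interferon response genes fell in macrophages: 16 of 29 were called lower and 0 higher, or 22 when adjusted over the list alone. Ifit3 fell by 2.15 ± 0.24 on the log2 scale (adjusted p = 6.34e-04), Rtp4 by 1.51 ± 0.17, Oasl2 by 1.19 ± 0.12 and Irf7, a transcription factor of the type I interferon response, by 1.09 ± 0.14. The list had a camera adjusted p of 4.95e-26 and an adjusted p of 0.0174 with an estimated correlation. MHC class II genes fell in 5 of 15 (10 when adjusted over the list alone), among them H2-Ab1 from 203 ± 23.8 to 89.3 ± 32.9 CPM (-1.19 ± 0.20, adjusted p = 0.00744), H2-Aa (-1.16 ± 0.24), H2-DMa (-0.60 ± 0.10) and the invariant chain Cd74 (-1.02 ± 0.22). That list had an adjusted p of 6.01e-08, and 0.0188 with an estimated correlation. Markers of other cells moved lower beside it, dendritic cell markers (median -0.39, adjusted p = 0.00865) and monocyte markers (median -0.40, 0.0253), though with an estimated correlation neither was called (0.0821 and 0.327). B-cell markers were not called (median -0.46, 0 of 5 called, 0.151; 0.28 with an estimated correlation), and were called lower with 2 library sets (0.0091) or 3 (0.011) as a covariate. Adhesion and migration genes fell in 6 of 19 (7 when adjusted over the list alone), among them the chemokine receptors Ccr2 (-1.20 ± 0.23, adjusted p = 0.0165), Ccr1 (-0.76 ± 0.16) and Cx3cr1 (-1.58 ± 0.37), with adjusted p of 5.21e-06 for the list and 0.00594 with an estimated correlation.

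Across all genes in macrophages, 142 rose and 200 fell of 14543 tested, 8 of them rising and 50 falling at least 2-fold, and 2062 (14.2%) had an unadjusted p under 0.05. The groups did not overlap in 492 genes (3.38%), where chance gives 0.43%. Besides Abcg1, Cd36, Abca1 and Psap, the rises that led the comparison were those of Gstm3, a glutathione transferase (0.92 ± 0.19, adjusted p = 0.0229), Tst (0.81 ± 0.18), Panx1, a membrane channel (0.77 ± 0.13), and P2ry1, a nucleotide receptor (0.74 ± 0.16). Besides Cx3cr1, Rtp4, Sqle and Insig1, falls that led it were those of Ccr3 (-1.97 ± 0.28, adjusted p = 0.0025), Ifit2 (-1.52 ± 0.25) and Rn7sk, a small nuclear RNA (-1.41 ± 0.26, 0.0122). The count was 150 without vehicle replicate B or E, 187 without ox-LDL replicate L and 188 without ox-LDL replicate H. Of 23 alternatives (22 for Tst and Ifit3), Insig1, Sqle, Cyp51, Mvd, Abcg1, Srxn1, Cat, Ifit3, Rtp4, Oasl2, Irf7, H2-Ab1 and H2-DMa lost their calls in 0, and Cd36, Mylip, Prdx1 and Txnrd1 in 1, the fit over all 4 groups. That fit also ended the calls of Tst (10 in all, the others without A, B, C, D, E, G, H, K or L), Abca1 (9, without B, C, D, E, G, H, K or L), Psap (8, without B, C, E, G, H, K or L), P2ry1 (7, without B, E, G, H, J or L) and Ccr1 (5, without B, C, E or L). It ended those of Gstm3 (5, without C, D, E or H), Ccr2 (3, without B or E) and Hsp90b1 (9, without A, B, D, E, G, H, I or K). Sesn2 lost its call in 11, among them without B, C, D, E, G, H, J, K or L, and Cx3cr1 in 11, among them without any one library other than K. Cd74 lost it in 7, without B, C, D, E, G, H or L, and H2-Aa in 5, without B, C, D, G or L. With total counts in place of TMM factors 92 rose and 334 fell, and in 1 fit over all 4 groups 6 rose and 74 fell. Other fits called more genes in both directions: 305 rose and 393 fell with DESeq2, and 256 and 323 with limma voom. In fits added after the data were seen, these were 309 and 498 with 2 library sets, 385 and 607 with 3, and 657 and 822 with surrogate variables.

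Pak1, a kinase of membrane ruffling (-0.31 ± 0.07, adjusted p = 0.0419), and Ncf4 of the NADPH oxidase (-0.36 ± 0.09, 0.0431) were called lower in macrophages. They were 2 of 41 in the macropinocytosis list (2 when adjusted over the list alone), which was not called itself (adjusted p = 0.394). Pak1 lost its call in 13 of 23 alternatives, among them without A, B, C, D, E, G, H, I or L, with an adjusted p up to 0.436. Ncf4 lost it in 11 of 23, among them without A, B, D, E, G, H, I, J or L, with an adjusted p up to 0.356. Among the other preset genes, Hmox1 (0.35 ± 0.12, adjusted p = 0.177), Il1b (-0.95 ± 0.45, 0.364), Ly6c2, Adgre1, Csf1r and Cybb were not called.

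**Figure D3:**
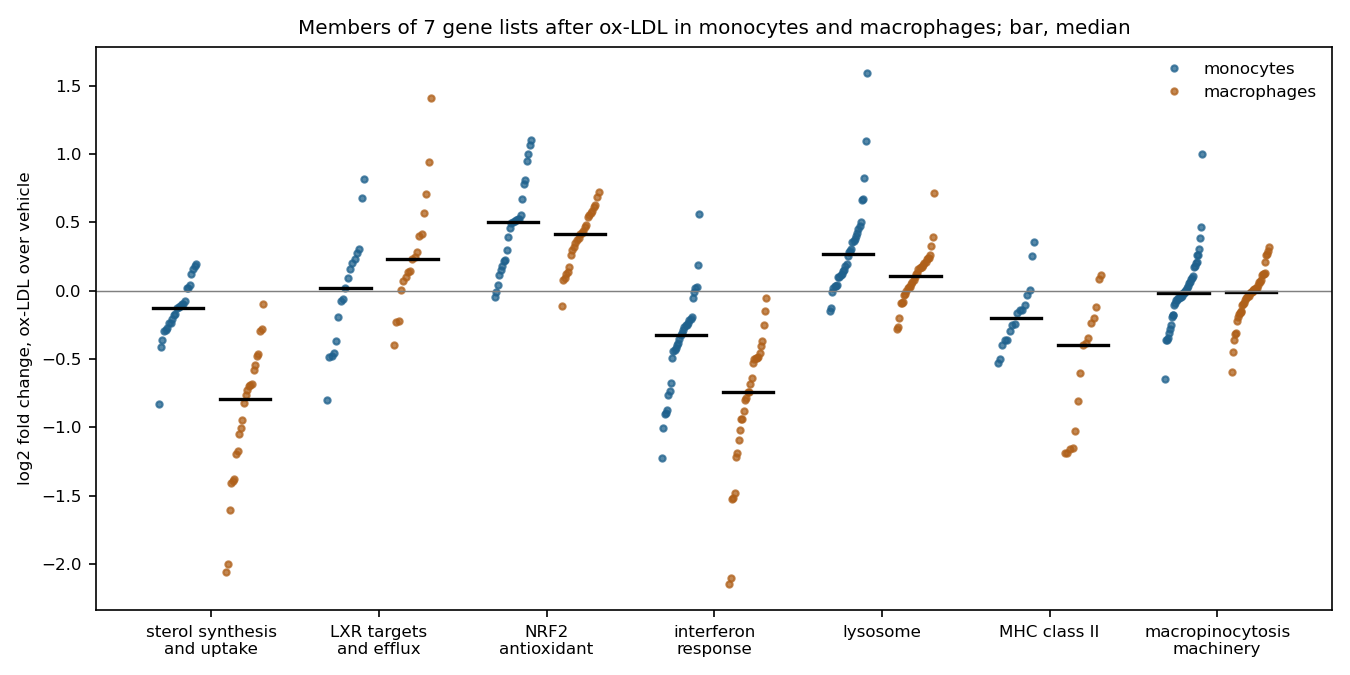
Log2 fold change of ox-LDL over vehicle for each tested member of 7 gene lists, in monocytes and in macrophages, with the median as a bar. The median of the sterol list is -0.12 in monocytes and -0.79 in macrophages, and that of the NRF2 list 0.50 and 0.42.

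The direct comparison of the ox-LDL effects asked where macrophages and monocytes responded differently. Sterol genes fell further in macrophages. For Insig1 the log2 change in macrophages minus that in monocytes was -1.16 ± 0.19 (adjusted p = 0.019); its monocyte means were 47.7 ± 9.64 CPM with vehicle (n = 6) and 40.7 ± 8.23 with ox-LDL (n = 5). It was -1.45 ± 0.26 for Idi1 (0.0354), -1.40 ± 0.27 for Sqle (0.0444) and -1.19 ± 0.21 for Msmo1 (0.0354). Of 24 sterol genes 7 were called lower and 0 higher, or 14 when adjusted over the list alone, and the list had an adjusted p of 1.68e-26 and of 0.00747 with an estimated correlation. Also among the 7 were Cyp51 (-1.08 ± 0.20) and Stard4, a cholesterol carrier (-0.95 ± 0.18), named outside the rule after their values were seen.

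Outside the sterol list 4 genes were called. Rn7sk had a difference of -2.22 ± 0.36 (adjusted p = 0.019; chromosome 9, 78175303 to 78175633), at 37.1 ± 10.3 and 65.2 ± 17.9 CPM in monocytes with vehicle and ox-LDL and 11.9 ± 5.30 and 4.49 ± 0.787 in macrophages. Zfp217, a zinc-finger gene, had a difference of 1.21 ± 0.22 (0.0354), at 21.0 ± 4.20 and 9.15 ± 1.95 CPM in monocytes and 6.26 ± 0.972 and 6.31 ± 0.440 in macrophages. Gm24447, an Rn7sk copy (-2.12 ± 0.39), and the histone gene Hist1h4c (-1.95 ± 0.35, under 2.1 CPM in every group mean) are named after their values were seen. In all 11 of 17466 genes were called, 1 higher and 10 lower, and 1261 (7.2%) had an unadjusted p under 0.05. The count was 1 without monocyte ox-LDL replicate 8 or 9 or macrophage vehicle replicate A, 3 without monocyte 1 or 6 or macrophage C, H or K, 4 without D, I or L, 5 without B or E, 6 without G and 7 without monocyte 5. It was 18 without monocyte ox-LDL replicate 7 (2 higher and 16 lower) and 44 without replicate 10 (23 higher and 21 lower). The excess of lower genes stayed with DESeq2 (16 higher and 44 lower) and with 3 library sets as a covariate (22 and 80). With limma voom it was 23 higher and 24 lower, and without the 4 monocyte libraries high in neutrophil markers 85 higher and 44 lower, so the excess of lower genes depended on these choices. Of 32 alternatives, Insig1 and Rn7sk lost their calls in 3, Msmo1 in 12, Idi1 in 16, Sqle in 19 and Zfp217 in 20, with adjusted p up to 0.133.

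Cd36 did not pass the test of the difference (-0.80 ± 0.24, adjusted p = 0.37), nor in any of 32 alternatives (adjusted p from 0.0733 to 0.637). Plin2 did not pass it in the fit reported here (-0.96 ± 0.19, adjusted p = 0.0655) and passed in 7 of 32 alternatives (adjusted p from 0.00144 to 0.198), so its call depended on the fit. Those were DESeq2, limma voom, 2 library sets (-0.94 ± 0.18, adjusted p = 0.0153) or 3 (-0.89 ± 0.14, 0.00354) as a covariate, and fits without monocyte replicate 7, without 10 or without the 4 libraries. The NRF2 list was not called in the test of the difference either (camera adjusted p = 0.406). Interferon response (1.2e-05) and MHC class II (1.5e-04) lists moved lower in macrophages relative to monocytes by camera, with adjusted p of 0.296 for both with an estimated correlation. Across the 13989 genes in both fits the log2 fold changes had a Pearson correlation of 0.219 and a Spearman correlation of 0.231; this is across genes, which are not independent replicates. Of 338 genes called in macrophages and tested in monocytes, 273 (80.8%) had the same sign in monocytes. The 2 effects share no library.

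The comparison of vehicle macrophages with vehicle monocytes addressed differentiation, to which culture time and PMA also belong. Macrophages held more transcripts of lysosomal and lipid-handling genes: Gpnmb, a lysosomal glycoprotein, at 19980 ± 2365 CPM (n = 5) against 1427 ± 427 (n = 6), a log2 fold change of 3.79 ± 0.19 (adjusted p = 1.27e-09). Ctsd stood at 19170 ± 1202 against 2602 ± 524 CPM, Apoe at 26100 ± 8256 against 4206 ± 883 and Cd36 at 2.42 ± 0.17 on the log2 scale. Of 32 lysosome genes 24 were higher and 2 lower (5.66e-08; adjusted p = 0.0809 with an estimated correlation). Of 21 macrophage markers 16 were higher and 2 lower (6.43e-05; adjusted p = 0.214 with an estimated correlation), such as Trem2 (3.98 ± 0.22). Monocyte libraries held more MHC class II transcripts: 15 of 16 genes were lower in macrophages (5.63e-07; adjusted p = 0.13 with an estimated correlation), such as H2-Aa at 108 ± 16.9 against 2908 ± 368 CPM and Cd74 at 679 ± 107 against 15780 ± 2574. Of 24 sterol genes 19 were lower in macrophages and 3 higher (5.01e-04; adjusted p = 0.256 with an estimated correlation), such as Fdft1 (-2.35 ± 0.10) and Idi1 (-2.94 ± 0.13).

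The rises that led this comparison were Fcrls (111 ± 94.5 against 0.277 ± 0.174 CPM), Mamdc2, Npy, Apbb2 (6.29 ± 0.36 on the log2 scale), Adra1a, Atp6v0d2 of the vacuolar proton pump (273 ± 70.6 against 3.51 ± 1.09 CPM), Plscr4 and Spp1, osteopontin (1947 ± 247 against 27.0 ± 17.3 CPM). Those that were lowest in macrophages were Retnlg (1622 ± 2002 CPM in monocyte libraries and 3 counts in all 5 macrophage libraries), S100a9 (3300 ± 3824 against 0.347 ± 0.407 CPM), Hbb-bs, Hba-a2, Asprv1, Apol7c (3035 ± 400.1 against 0.156 ± 0.0891), Ptk6 and Apol7a (at least 3010-fold lower, with 0 counts in macrophages). Their cells of origin were not tested. All 15 neutrophil markers tested (7.71e-07; adjusted p = 0.28 with an estimated correlation), 16 of 18 B-cell markers (0.249 with an estimated correlation), 11 of 11 NK-cell markers (0.0772), 10 of 12 erythroid markers (0.13) and 10 of 14 dendritic cell markers (0.0772) were lower in macrophages. Among the last, Ccr7 stood at 7179 ± 1259 against 2.34 ± 1.78 CPM, Fscn1 at 2547 ± 650.3 against 2.01 ± 1.29, and Flt3 at 316 ± 47.5 against 0.130 ± 0.162.

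In total 4645 genes were higher and 5724 lower in vehicle macrophages of 16288 tested, and 2422 and 3764 at least 2-fold. With ox-LDL in both cell types 4799 were higher and 5545 lower of 15825, and 2512 and 3418 at least 2-fold. The macropinocytosis list was not called in either comparison (13 of 41 higher and 12 lower with vehicle, adjusted p = 0.243; 16 higher and 10 lower with ox-LDL, 0.295). With ox-LDL, Fcrls, Apbb2, Mamdc2, Atp6v0d2, Ltbp3, Speg, Siglec1 (5.49 ± 0.17, adjusted p = 3.29e-11) and Rapsn led the rises, and Retnlg (at least 119000-fold lower), Pglyrp1, Scin, Ly6d, Apol7c and haemoglobin genes were the lowest. In that comparison 22 of 24 sterol genes were lower in macrophages and 2 higher (1.86e-06; adjusted p = 0.193 with an estimated correlation), such as Cyp51 (-3.16 ± 0.17) and Mvd (-2.50 ± 0.14). Of 17 LXR targets 12 were higher and 2 lower (9.62e-04; adjusted p = 0.112 with an estimated correlation), such as Abca1 (3.79 ± 0.26). No list was called in either comparison with an estimated correlation. Cell type, culture time and PMA cannot be separated in these comparisons. Part of each contrast lies in marker genes of other cell types that were abundant in the monocyte libraries, and their cells of origin were not measured.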

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

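The counts over other splits of the libraries, and the tests of library depth, of neutrophil markers, of other cell types' markers, of dilution by other cells, of sterol transcripts of unresponsive cells and of other small RNAs, were chosen or read only after the result they weigh was seen. The tests of the sterol genes without the 4 libraries and of words shared between Rn7sk copies were set before theirs was seen. The sizes of the differences, the library values and the splits below come from the fits described with the comparisons.

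Of 100 splits of the monocyte libraries, 5 called at least the 4 genes of the real one, so chance was not excluded for that count. The highest of the other splits called 1104 genes and put replicates 5, 6, 10 and 11 together, a structure of the samples. Within 3 library sets, with the sets as a covariate, 3 of 100 splits called as many as the real 227, and the highest other called 1308. The sets were clustered from residuals around the real group means and kept for every split. That can favour the real split, so this count cannot exclude chance. In macrophages 2 of 100 splits, the real one included, called at least 342, which is under 5 of 100. The other one called 542 and put C, D, I and J on the same side. A split along the structure of the libraries can thus call as many genes, so chance was not firmly excluded for that count. Within 3 sets, with the limit given for the monocyte sets, the real 992 was reached by 1 of 100 splits, the real one. The highest other called 188. For macrophages against monocytes only the real split, 1 of 100, reached 10369 with vehicle and 10344 with ox-LDL, and the others called 0. Every other split put both cell types in the same group, which widens the spread within groups and leaves few genes to call. These counts were therefore largely fixed in advance and cannot weigh chance. For the difference of effects 5 of 100 reached the real 11, so chance was not excluded, and the highest other called 499. Within sets 4 of 100 reached 102, with a highest other of 245, which cannot exclude chance for the reason given for monocytes. The same sign in monocytes for 80.8% of macrophage-called genes was reached by 3 of 100 splits of the monocyte libraries, with a highest other of 83.4%. That is under 5 of 100, but further splits gave 80.5%. The margin was narrow, so chance was not firmly excluded.

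The monocyte libraries formed sets that cross the treatment, replicates 5, 6, 10 and 11 against the rest. Of 18 neutrophil markers, 15 (83.3%) were higher in each of these 4 libraries than in all 7 others, so a candidate explanation is neutrophil or granulocyte precursor RNA; the summed markers averaged 38550 CPM in the 4 and 5730 in the 7, and the most abundant, Ngp, S100a8 and S100a9, averaged over 3000 CPM in vehicle monocytes. Of the 4 totals, 2 lay inside the range of the other 7 and the rest above it. Yet each of the 4 held 30580 to 46450 CPM of neutrophil markers, against 4989 to 6131 in the 7. These values argue against depth as the cause for the neutrophil markers. For other genes that differ between the sets, depth stays open. Dendritic cell markers were 0.744 times as high in the 4 and monocyte markers 2.5 times as high. These ratios cannot decide whether the share of the main cell type was lower there. Other cell types need not rise alike, and which cell type was the main one was not measured. The labels name no sort or gate, and no biological explanation was tested.

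Sterol synthesis genes fell with ox-LDL in macrophages more than in monocytes. A dilution of every monocyte response by the same factor is argued against only if undiluted monocytes and macrophages would respond alike. That was not measured. The mean NRF2 change in monocytes was 1.253 times that in macrophages (jackknife SE 0.137) and the mean sterol change 0.15 times (SE 0.049). Interferon genes, at 0.414 times (SE 0.070), lay on the side dilution needs and lysosome genes, at 3.18 times (SE 1.23), on the other. The 4 libraries high in neutrophil markers are not the cause, since the median difference over the sterol list was -0.811 without them. Sterol transcripts of cells in the monocyte libraries that do not respond remain open: their sum in monocytes was 2.26 times that in macrophages with vehicle, and no sorted fraction was measured. Cell type, culture time and PMA differ together between the groups, so a biological difference stays open and untested.

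Rn7sk and a copy differed in the same test, Rn7sk falling in macrophages. The copies share at least 15.7% of their 25-base words with Rn7sk (Gm24447 69.1%, Gm26035 55.3%, Gm24146 38.0%), so reads shared between them cannot be told apart from separate changes for the copies. Carry-over of RNA without poly(A) tails, which a polyadenylated-RNA protocol should leave out, may also be involved. The median difference over 34 other small RNA genes was -0.553 (SE 0.225), with 0 called, too wide to decide. Of these, 12 were tested in the macrophage comparison, with a median log2 change of -0.259. Histone genes such as Hist1h4c were not among them. Neither shared reads nor carry-over was excluded, and no biological explanation was tested.

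The effect of ox-LDL differed between the cell types in a direct test for 11 genes, among them 10 with log2 differences (macrophages minus monocytes) of -1.16 for Insig1, -2.22 for Rn7sk, -1.19 for Msmo1, -1.95 for Hist1h4c, 1.21 for Zfp217, -1.45 for Idi1, -1.08 for Cyp51, -2.12 for Gm24447, -1.40 for Sqle and -0.95 for Stard4. By camera the sterol list differed (adjusted p = 1.68e-26), as did interferon response (1.2e-05), MHC class II (1.5e-04), lysosome (0.0022), macrophage markers (0.0022), scavenger and lipoprotein receptors (0.0171), adhesion and migration (0.0172), lipid storage (0.03), matrix and proteases (0.03) and erythroid markers (0.03), all lower in macrophages, and LXR targets (0.0358), higher. Of these lists only the sterol one was called with an estimated correlation; the others had an adjusted p of at least 0.296.

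Single libraries lay far from the rest of their group (a gap to the nearest library that fills most of the group's range) in 13 of 310 tests over counted genes, totals, mitochondrial shares, marker sums and the genes named here, or 4.2%, where chance gives about 1 in 20. Vehicle macrophage C held counts for 21520 genes (nearest 20860), and ox-LDL macrophage I 0.551 CPM of NK-cell markers (nearest 1.75). In vehicle monocytes, replicate 6 held 2277 CPM of Gpnmb (nearest 1399) and 7353 of Psap (3578), and replicate 1 held 1972 of Hmox1 (1454). In ox-LDL monocytes, replicate 10 held 7328 CPM of Psap (nearest 3759) and replicate 7 held 155.6 of Ly6d (80.9). Vehicle macrophage A held 48.9 CPM of H2-DMa (nearest 36.4). Near the floor, vehicle macrophage D held 0.452 CPM of Hba-a2 (nearest 0.0468), 0.547 of Hbb-bs (0.108) and 0.0713 of Retnlg (0), vehicle macrophage E 0.0221 of Ptk6 (0) and ox-LDL macrophage K 1.09 of Ngp (0.0272).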

How the results depend on the processing

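The covariates of library sets or surrogate variables and the fits without a set of libraries were chosen after the data were seen. Several codings were tried and each is given. No result changed direction on a called side. In monocytes, where 4 genes were called, the count was 9 without a filter, 14 with the stricter filter, 30 with limma voom, 161 with DESeq2, 259 in 1 fit over all 4 groups, 122 with 2 library sets, 227 with 3, 1051 with surrogate variables and 0 without the 4 libraries high in neutrophil markers, and 0 to 8 without any one library. In macrophages, where 342 were called, it was 698 with DESeq2, 579 with limma voom, 80 in 1 fit over all 4 groups, 58 at 2-fold, 807 with 2 sets, 992 with 3 sets, 768 with sets read from the principal components and 1479 with surrogate variables, and 150 (without B or E) to 348 (without I). For the difference of effects, with 11 called, it was 5 with total counts, 60 with DESeq2, 47 with limma voom, 63 with 2 sets, 102 with 3 sets and 129 without those 4 monocyte libraries, and 1 (without 8, 9 or A) to 44 (without 10). For macrophages against monocytes only the 2-fold threshold moved the count by over 1.5 times, to 6186 with vehicle and 5930 with ox-LDL, by its construction. For the rest the cause was not tested, except that fewer libraries entered the fits that left some out. The macrophage split between rises and falls moved from 41.5% higher to 21.6% with total counts and to 7.5% in 1 fit over all 4 groups.

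Among named genes, 37 of 3302 planned results fell short of the threshold they had passed and 28 passed it newly; over left-out libraries these were 240 and 4 of 6056, and over the added fits 16 and 85 of 1504. Among lists they were 88 and 18 of 1115 planned, 66 and 33 of 1942 with a library left out and 27 and 19 of 487 added. A gene or list on the uncalled side in both fits was counted as unchanged whatever its sign. No paired analysis was possible because the groups share no replicate number that would pair single libraries. Fits within sets of libraries read from the data, which cross the treatment, were run and are given above. Libraries of a group were unequally alike in their gene counts. The Pearson chi-square per degree of freedom ran from 8.6 (G and H) to 126.1 (A and D) in macrophages. In monocytes it ran from 23.4 (3 and 4) to 402.9 (11 and 7). Libraries of a group may therefore not be independent, which leaving out 1 at a time does not test. In simulated data 44% of 2-fold changes were recovered in monocytes and 68% in macrophages. Smaller changes at this depth and spread were therefore often missed in data without library sets, and recovery in the real libraries was not measured.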

Other observations

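The counts of alternatives given in this part include the fits that were chosen after the data were seen. Macrophages given ox-LDL also showed small rises in glycolysis genes: Pgam1 rose from 203 ± 9.15 to 266 ± 6.67 CPM (log2 fold change 0.39 ± 0.05, adjusted p = 0.00146), Pgk1 by 0.28 ± 0.06 (0.0229) and Hk3, a hexokinase, by 0.55 ± 0.12 (0.0313), 3 of 25 in the list (4 when adjusted over the list alone). The list had a camera adjusted p of 0.00335, and 0.222 with an estimated correlation. In lipid storage and fatty acid use, the lysosomal lipase Lipa rose (2922 ± 176 to 3602 ± 165 CPM, 0.30 ± 0.06, adjusted p = 0.0248) and the acyl-CoA synthetase Acsl3 fell (-0.67 ± 0.13, 0.0174), among 25. That list had an adjusted p of 0.0145, and 0.295 with an estimated correlation. Oxidative phosphorylation moved higher by camera (0.00134; 0.439 with an estimated correlation) with 0 of 28 called. Pgam1 and Acsl3 lost their calls in 1 of 23 alternatives, the fit over all 4 groups. Lipa lost it in 8, among them without D, E, H or L, Pgk1 in 8, among them without B, C, D, E or H, and Hk3 in 9, among them without A, B, C, E, G, H, I or L.

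Marker genes of macrophages and monocytes moved with ox-LDL too. The Fc receptor Fcgr1 fell (-0.60 ± 0.13, adjusted p = 0.0322) and the complement gene C1qc fell (-0.40 ± 0.09, 0.0402), 2 of 21 macrophage markers, a list that was not called (0.151). Ace, a peptidase, rose from 1.57 ± 0.528 to 4.55 ± 1.55 CPM (1.54 ± 0.28, adjusted p = 0.0131) while Ccr2 and Cx3cr1 fell, among 17 monocyte markers (0.0253; 0.327 with an estimated correlation). Tcf4, a transcription factor of plasmacytoid dendritic cells, fell (-0.50 ± 0.08, adjusted p = 0.00559), 1 of 10 dendritic cell markers (0.00865; 0.0821 with an estimated correlation). Ace lost its call in 1 of 22 alternatives and Tcf4 in 1 of 23, the fit over all 4 groups in both cases. Fcgr1 lost it in 7, among them without B, E, H, J, K or L, and C1qc in 9, among them without A, B, D, E, G, H, J or L.

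The other lists were not called with ox-LDL in macrophages: inflammatory cytokines (adjusted p = 0.394, 0 of 19 called), cell cycle (0.269), matrix and proteases (0.666), immediate-early and heat-shock genes (0.269), mitochondrial transcripts (0.997), B-cell (0.151), T-cell (0.637) and platelet markers (0.394). Markers of plasma cells, NK cells, neutrophils, erythroid cells, stroma, endothelium and mast cells had too few tested members there. In monocytes the lists not yet given were not called: scavenger receptors (0.0912), inflammatory cytokines (0.7), cell cycle (0.9), adhesion and migration (0.145), glycolysis and hypoxia (0.15), immediate-early and heat-shock genes (0.975), mitochondrial transcripts (0.9), monocyte (0.0645), plasma cell (0.369), T-cell (0.942), NK-cell (0.59), neutrophil (0.9), dendritic cell (0.253), erythroid (0.181), platelet (0.369), stromal (0.942), endothelial (0.594) and mast cell markers (0.9). With library sets as a covariate, chosen after the data were seen, some of these passed: monocyte markers lower (0.00903 with 2 sets, 8.09e-04 with 3), adhesion and migration lower (0.0442 and 0.0157), and with 3 sets erythroid (0.0405) and plasma cell markers (0.0372) higher.

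Between vehicle macrophages and vehicle monocytes, other lists moved by camera as well. Lower in macrophages were inflammatory cytokines (16 of 26 called lower and 1 higher, adjusted p = 0.00102), interferon response (20 of 32 lower and 5 higher, 0.0113), T-cell markers (15 of 18 lower and 2 higher, 6.43e-05), monocyte markers (14 of 19 lower and 3 higher, 0.00166) and immediate-early and heat-shock genes (15 of 23 lower and 2 higher, 0.0113). The last had an adjusted p of 0.0119 with ox-LDL in both cell types, where mitochondrial transcripts were lower too (9 of 12 lower and 0 higher, 0.018; 0.103 with vehicle). Higher were scavenger and lipoprotein receptors (14 of 20 higher and 4 lower, 0.00246), lipid storage and fatty acid use (16 of 25 higher and 4 lower, 0.00171), LXR targets (10 of 17 higher and 2 lower, 0.00359) and glycolysis and hypoxia (15 of 25 higher and 4 lower, 0.0113). With an estimated correlation the lists given with vehicle as called had adjusted p from 0.0772 to 0.426, and no list was called with ox-LDL.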
